A study of Mus musculus with 2 samples.

How the data were processed

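Polyadenylated RNA longer than 200 nucleotides, also depleted of ribosomal RNA, was sequenced from the stomach of 8-week-old C57BL/6J mice, as strand-specific paired reads of 76 nucleotides with RNA spike-ins added, per the labels. Both libraries belong to 1 group and carry biological replicate numbers 1 and 2. The labels give each its own tissue sample and describe both as pools of males and females. They also give both the same donor record, so how far the pools are independent animals is not known, and the spread reported here is that between these libraries.

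The expected counts per gene and per transcript were deposited as 1 table per library, made from alignments to the transcriptome on mm10 with GENCODE M4 gene models, per the README beside the tables. They are fractional because reads shared between genes were divided by a model. The column names are those that RSEM writes. The quantifier's version and the aligner are not given in the sources used here. The deposited TPM values are relative to the total of all transcripts of a library, spike-ins included, and the authors deposited FPKM values per gene as well. A posterior mean TPM and a posterior standard deviation of the count stand in the same tables, per the file headers, and the latter shows how far reads shared between genes leave a count open. The percent that each transcript holds of its gene was also deposited by the authors, and the shares given here were computed from transcript TPM. The authors deposited a splice junction table on mm9 with counts of reads per junction, and each count equalled the sum of the numbers R1 and R2 in the junction's name. The sources used here do not tie R1 or R2 to a library. The deposited contig table, also on mm9, gives a signal that is proportional to summed coverage over contig length, except in 2 contigs whose summed coverage stands at the highest value of that field, 1073741823. Both mm9 tables carry a significance field, which was taken as a reproducibility value (0.1 or lower passing) without a definition in the sources used here. No coordinates were converted between builds.

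Each gene table held 69691 features, of which 43346 were mouse genes, 96 were spike-ins, 1 was the phage phiX174 and 26248 carried numeric IDs and had a count of 0 in both libraries. Spike-ins took 1.14% and 1.12% of the expected counts of replicates 1 and 2, and phiX174 took 0.252% and 0.185%. These rows stayed out of library sizes for count-based ratios. Symbols, biotypes and mm10 positions came from GENCODE M21, a later release on the same build, through unversioned gene IDs, and 42462 of the 43346 IDs (98.0%) had a symbol. GC content and length were those of M21 transcript sequences, which 99.2% of protein-coding genes with a mean TPM of at least 1 had.

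With 1 group of 2 libraries no contrast between groups exists and no p-value was computed across genes. Levels are given as mean TPM ± SD (n = 2). Differences between the replicates are log2 ratios, replicate 2 over replicate 1, of scaled counts (CPM) with a prior count of 2 after TMM scaling in edgeR 4.0.16, on expected counts rounded to whole numbers. Each ratio has an exact conditional binomial (Clopper-Pearson) interval at 95%, which covers counting error only, since reads without molecular identifiers are not independent molecules. The spread was the common dispersion of edgeR, with genes kept by filterByExpr, and DESeq2 1.42.0 gave an alternative. Fixed gene lists, 39 in number with 360 genes, were compared with 10000 random lists of the same size. For levels these were drawn from protein-coding genes, and for ratios from 20 bins of mean expression. The percentile describes these libraries and is not a test. A list is described as outside the middle 95% of random lists, and lists with fewer than 3 members at a mean TPM of at least 1 had no ratio.

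Genes named in the text followed a rule. It took the 25 genes of highest mean TPM, up to 6 members of highest TPM of each list with up to 2 below TPM 1 in both libraries, and the 12 highest and 12 lowest ratios of protein-coding genes with a mean TPM of at least 5. It also took preset isoform genes, the 5 genes with the largest difference in a transcript share among genes with a mean TPM of at least 20, and the sex-linked list in full. The lists, the rule, the tests and the alternatives were fixed before the data were examined, apart from those the closing part names. Genes named outside the rule are marked as such.

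The mm9 junctions were tied to named genes only where at least 2 junctions on the same chromosome and strand had the lengths and the spacing of that gene's M21 introns. The procedures were tested on simulated data, drawn for this pair of libraries from the real means and library sizes with a coefficient of variation of 0.3. Over 15560 genes edgeR returned 0.311 and the median of the DESeq2 gene-wise values 0.189. Of 100 genes raised 3-fold, 78% passed a 2-fold limit, and of 100 genes lowered to 0.25 of their level 94% did, against 11.5% of 6637 unchanged genes. Lists were also tried, of genes drawn at random with independently simulated ratios. Of those left unshifted, 4.25% fell outside the middle 95% of matched lists. Of those shifted by 1 on the log2 scale, 96.5% fell above that range. These rates do not cover lists whose members vary together. Of 2000 counting intervals, on counts drawn anew with counting error alone, 95.7% held the true ratio. This check does not cover the spread between replicates. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and R 4.3.3 were used. Alternatives covered pseudocounts, expression minimums, scaling, FPKM and posterior means, random-list pools, leaving out each replicate, and limits on the significance field.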

Results

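Gene expression was measured in 2 libraries of polyadenylated RNA from the stomach of adult C57BL/6J mice, a common inbred laboratory strain. Replicate 1 held 52363597 expected read pairs and replicate 2 held 62452468. At these depths 3 read pairs on a transcript of 1 kb corresponded to a TPM of 0.0519 in replicate 1 and 0.0437 in replicate 2. The labels name no other tissue or condition, so the questions that the design allows are which genes the stomach expressed, at what level, and how far the replicates parted.

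The genes of a lipase cofactor and of a protease precursor dominated the stomach transcriptome. Clps, which encodes the lipase cofactor colipase (chromosome 17, 28558149 to 28560766 on mm10), had a TPM of 236635 ± 59759 (SD, n = 2). Pgc, which encodes the protease precursor progastricsin of chief cells (chromosome 17, 47726842 to 47734482), had a TPM of 124897 ± 33353. Both were higher in replicate 2, where Clps stood at 278891 against 194378 and Pgc at 148481 against 101314. Pla2g1b, a secreted phospholipase (chromosome 5, 115466262 to 115474722), had a TPM of 27215 ± 9262.

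Sprr2a2, a cornified envelope gene (chromosome 3, 92215920 to 92256724), ranked directly after Clps and Pgc by mean TPM, at 47869.9 ± 25383, with 65818 in replicate 1 and 29922 in replicate 2. Genes of the surface mucous (pit) cells, which coat the gastric lining, were also abundant. Tff1 (chromosome 17, 31161395 to 31165277), a trefoil peptide, had a TPM of 29206 ± 3227, Psca 19508 ± 2947, Gkn1 14818 ± 3236 and Gkn2 7230 ± 1494. Ferritin genes, Fth1 at 4677 ± 1833 and Ftl1 at 4301 ± 615, and Actb at 5285 ± 1218 were also among the 25 most abundant genes, as were the ribosomal protein gene Rplp1 at 6496 ± 54.7 and Tff2 at 3642 ± 1115. The respiratory chain and ATP synthase genes Atp5d, Cox6a1, Atp5b and Cox8a lay between 2715 and 3616 TPM. The most abundant Atp5b transcript had 343 bases, so the TPM of Atp5b depends on reads being assigned to a short transcript. Cnfn had a TPM of 3139 ± 1243 and Pfn1 2414 ± 1434. The noncoding genes Gm42418, Rn7sk, Rn7s1 and Rn7s2 and the pseudogene Gm29216 had mean TPM between 4236 and 5845. Whether the reads counted for Gm42418 and Gm29216 were transcribed from these genes was not tested. The near-identical copies Rn7s1 and Rn7s2 had equal values, with a posterior standard deviation of 32.4% of the count in replicate 1 and 44.6% in replicate 2.

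The 10 most abundant genes held 52.6% ± 7.66 of transcripts (n = 2), the 50 most abundant 63.3% ± 5.35 and the 100 most abundant 68.1% ± 4.46. Clps and Pgc together held 30.0% in replicate 1 and 43.3% in replicate 2. With Clps and Pgc left out of the total, the 10 most abundant of the remaining genes held 27.0% ± 0.850. As a share of expected counts the 10 most abundant genes held 36.1% ± 6.71.

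**Figure D1:**
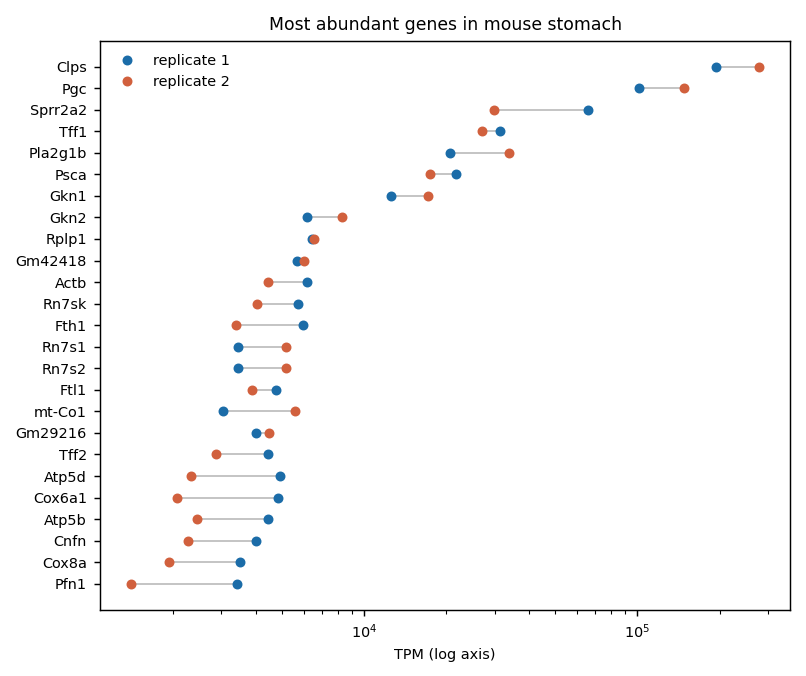
TPM (log axis) of the 25 genes with the highest mean TPM, one point per replicate joined by a line. Clps and Pgc lie farthest to the right, with 278891 and 148481 in replicate 2, and Pfn1 lies lowest with 1401 in replicate 2.

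In all, 10922 of 43346 genes reached a TPM of 1 in both replicates. Of these, 10499 were protein-coding, 187 were long noncoding and 158 were pseudogenes. Replicate 1 alone had 11358 genes at this level and replicate 2 had 11659.

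Cell types of the gastric gland were represented by abundant markers. Of the chief cell list 5 of 6 genes reached TPM 1 in both replicates, with Chia1, an acidic chitinase, at 2251 ± 652, Gif (intrinsic factor) at 671 ± 123, Pga5 at 106 ± 38.1 and the transcription factor gene Bhlha15 at 13.2 ± 3.52, while Lipf, the gastric lipase gene, had no reads in either library. All 9 pit cell genes were detected, with a median of 723 TPM; Ctse stood at 723 ± 41.1 and Muc5ac, the surface mucin, at 697 ± 280. All 4 neck and antral gland mucous genes were detected, among them Gkn3 at 829 ± 201, the gland mucin Muc6 at 220 ± 2.00 and Aqp5 at 49.0 ± 42.1. Of the 15 parietal cell genes, those of the acid-secreting cell, 14 were detected, led by the proton pump subunits Atp4a at 2043 ± 924 and Atp4b at 1796 ± 673 and the carbonic anhydrase Car2 at 1714 ± 198. Slc4a2 stood at 165 ± 14.8, Ezr at 101 ± 16.3 and Slc9a4 at 40.0 ± 22.0. The most abundant transcripts of Atp4a and Slc9a4 had 738 and 342 bases, and their TPM depends on that assignment. Slc9a4 had 24.5 TPM in replicate 1 and 55.6 in replicate 2, while its scaled counts had a log2 ratio of 0.59.

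Hormone genes led the enteroendocrine list. Gast (gastrin) had a TPM of 1319 ± 498, Sst (somatostatin) 949 ± 221, Ghrl (ghrelin) 824 ± 140 and Chga 217 ± 7.38, and 10 of 20 genes reached TPM 1 in both replicates. Pcsk1n stood at 25.3 ± 16.5, and Hdc, the histamine-forming enzyme, at 7.00 ± 1.49, while Tph1 and Pcsk1 stayed below 1. Of the 9 tuft cell genes 6 were detected, among them Ptgs1 at 20.2 ± 0.0424, Avil at 17.7 ± 2.21 and Trpm5 at 2.56 ± 0.587, while Dclk1 and Il25 stayed below 1. Receptors that regulate acid secretion had a median of 3.77 TPM over 7 genes, within the middle 95% of random lists (percentile 78.9), with Ptger3 at 8.67 ± 2.45, Sstr2 at 7.30 ± 0.707, Hrh2 at 5.16 ± 1.93, Chrm3 at 3.77 ± 0.283 and Cckbr at 3.07 ± 0.502, and Ghsr and Calcr had no reads. Of 14 stomach transcription factors 12 were detected, led by Klf4 at 248 ± 9.57, Barx1 at 146 ± 52.8 and Gata4 at 127 ± 16.2, with Klf5 at 82.6, Spdef at 72.7 and Foxa2 at 65.4, while Trps1 and Hnf4g stayed below 1.

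The list for the forestomach, the squamous part of the rodent stomach, was also represented. Of its 23 genes 22 were detected, with a median of 99.9 TPM, among them Sprr3 at 1207 ± 409, Lor (loricrin) at 668 ± 548, Sprr1a at 621 ± 101, Krt13 at 587 ± 61.0, Krt4 at 484 ± 102 and Krtdap at 469 ± 191. Dsg1a stood at 0.15. Whether squamous epithelium other than that of the forestomach contributed to these levels was not tested. Smooth muscle genes of the wall were all detected, with a median of 349 TPM over 12 genes, led by Tagln at 1541 ± 608, Acta2 at 1213 ± 197 and Actg2 at 1000 ± 339. Myl9 stood at 734, Cnn1 at 599 and Des at 573 TPM. All 7 fibroblast genes were detected, with Col1a2 at 78.7 ± 44.9, Col1a1 at 68.8 ± 0.806 and Col3a1 at 37.7 ± 3.62, as were 7 of 8 endothelial genes, with Egfl7 at 128 ± 8.22, Vwf at 29.4 ± 3.68 and Tie1 at 12.6 ± 2.69. Interstitial cells of Cajal, the pacemaker cells of the gut, were marked by Ano1 at 22.1 ± 3.75, Kit at 5.61 ± 0.559 and Etv1 at 1.34. Of 14 enteric neuron and glia genes 8 were detected, among them Uchl1 at 15.8 ± 6.23, Tubb3 at 7.71 and Sox10 at 4.28.

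Immune cell lists differed in level. No T cell gene reached TPM 1, and the highest, Cd4, had 0.64. Of the 9 B and plasma cell genes 4 were detected, with Igkc at 20.7, Igha at 17.2 and Ighm at 16.1 TPM. Macrophage genes were higher, with C1qc at 73.3 ± 22.6, C1qa at 40.8 ± 11.7 and C1qb at 37.9 ± 7.22, and so were MHC class II genes, with H2-Ab1 at 241 ± 149 and Cd74 at 217 ± 106. Of the 7 mast cell genes 5 were detected, with the proteases Mcpt1 at 29.2 ± 20.03 and Tpsb2 at 22.4 ± 10.03. Of the 8 interferon response genes 5 were detected, with Irf7 at 52.8 ± 19.5 and Isg15 at 8.06, and of the 8 genes of antimicrobial and secretory immunity 2 were, with Pigr at 6.01 and Lcn2 at 3.82. Hemoglobin genes Hba-a1, Hba-a2 and Hbb-bs had 169 ± 130, 147 ± 91.2 and 87.6 ± 59.9 TPM.

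Other lists gave the levels of general processes and of neighbouring tissues. Proliferation genes had a median of 6.06 TPM, within the middle 95% of random lists (percentile 90.4), with Ccna2 at 23.9 ± 8.89, Aurkb at 16.0 ± 0.445 and Mki67 below 1. Of the 16 pancreas acinar genes 9 were detected. After Clps the highest were Cela1 at 104 ± 0.226, Zg16 at 26.7 ± 7.85, Rnase1 at 14.8 ± 2.81 and Pnliprp1 at 13.7 ± 1.38, while Pnlip, the pancreatic lipase gene, stood at 0.37 and Cela3b at 0.77. The islet genes Ins1 and G6pc2 had no reads, and Ins2 had 5 read pairs in replicate 1 and 0 in replicate 2, while Pyy, a peptide also of gut endocrine cells, stood at 105 ± 6.46. Small intestine genes had a median of 0.30 TPM, with Apoa4 highest at 19.1 ± 8.01, and liver genes also had a median of 0.30, with Ahsg highest at 1.73. Adipose genes had a median of 7.33 TPM, with Cfd at 88.0 ± 54.0. Of the 9 striated muscle genes 7 were detected, with Acta1 at 559 ± 40.4 and Ckm at 213 ± 12.5. The kidney, brain and testis control lists had medians of 0.15, 0.66 and 0.0050 TPM, and of the 18 control genes only Mbp, at 14.0 ± 0.785, and Gfap, at 1.88 ± 0.636, reached TPM 1 in both replicates. Immediate early genes included Junb at 138 ± 52.1, Fos at 56.2 ± 10.6 and Jun at 40.4 ± 11.3, and 11 of 12 circadian clock genes were detected, with Nr1d1 at 42.4 ± 5.26. Of the 8 genes listed for non-polyadenylated RNA 7 were detected, with Rn7sk highest at 4881 ± 1186. Whether the RNA measured from these genes, histone genes included, lacked a poly(A) tail was not tested. Rmrp stood at 1959 ± 660, Rpph1 at 443 ± 146 and Hist1h2bc at 233 ± 61.5. The histone gene Hist1h4c stood at 12.2 and 6.23 in replicates 1 and 2, while Hist1h1b, at 0.12, was not detected. Rmrp is short, and its TPM rested on 0.0175% and 0.0131% of the read pairs of replicates 1 and 2. Ribosomal protein genes had a median of 165 TPM, nuclear genes of oxidative phosphorylation 265 and mitochondrial genome mRNAs 167, with mt-Co1 at 4299 ± 1781.

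Of the 39 lists, 17 had a median above the middle 95% of random protein-coding lists of equal size and none lay below it. Macrophage and dendritic cell genes and striated muscle genes were no longer above when random lists came from genes with a mean TPM of at least 1 (percentiles 92.8 and 84.8). Striated muscle genes were also not above in replicate 1 by itself (percentile 96.6).

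**Figure D2:**
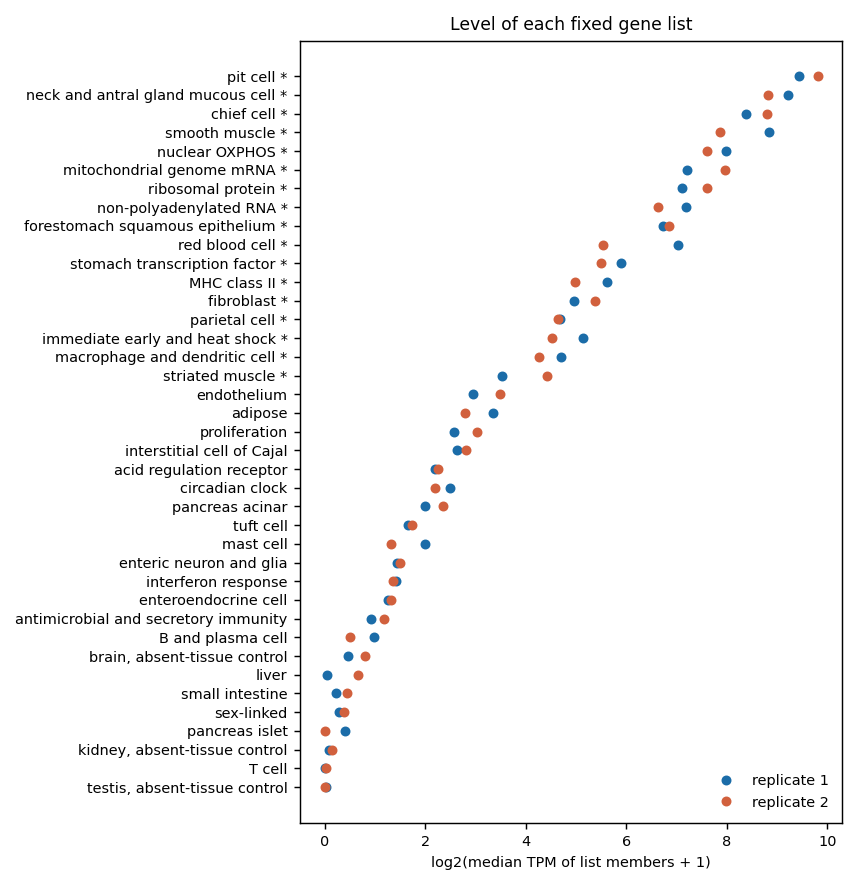
Median TPM over the members of each of the 39 gene lists, as log2(median TPM + 1), one point per replicate; an asterisk marks the 17 lists above the middle 95% of random lists. Pit cell genes lie highest, and the T cell and testis lists lie at the left end.

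The sex-linked genes were counted in both libraries, which the labels describe as pools of males and females. Xist, the noncoding RNA that coats the inactive X chromosome in females (X chromosome, 103460366 to 103483254), had 5 and 7 read pairs. The Y-linked genes Kdm5d, Eif2s3y, Uty and Ddx3y had 202 and 557, 101 and 171, 26 and 61, and 21 and 60 read pairs in replicates 1 and 2.

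Across genes, log2(TPM + 1) of the replicates had a Pearson correlation of 0.987 and a Spearman correlation of 0.952 over 43346 genes, which are not independent replicates. In a check for a library deposited more than once, which covers counting error alone, the chi-square was 257 per degree of freedom over 17195 genes with at least 10 read pairs, so the libraries were not counted as 1. The biological coefficient of variation was 0.293 over 15234 genes, and it was 0.25 for genes with a mean TPM of at least 5. Of 7047 genes with a mean TPM of at least 5, 92.7% differed by less than 2-fold. Spike-in controls held 1.24% ± 0.0354 of transcripts and 59 of 96 were seen in both libraries. Their log2(TPM + 1) had a Pearson correlation of 0.999 across the 96 controls. For 28 spike-ins with at least 1000 read pairs the log2 ratio between the replicates had an SD of 0.20, against 0.70 for 7914 genes of that depth.

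Genes that differed at least 2-fold were mostly higher in replicate 1. The 7047 genes above were not centred after scaling, with a median log2 ratio of -0.13. How much of the excess in replicate 1 this offset gives was not tested. Of the 7047 genes, 440 were higher in replicate 1 and 74 in replicate 2 (14.4% of those that differed), and 356 and 52 had a counting interval wholly beyond 2-fold. At a mean TPM of at least 1 the numbers were 657 and 321 (32.8%), and at 20 or more they were 281 and 29 (9.35%). Igfbp2, which encodes a binding protein of insulin-like growth factors, had 797 TPM in replicate 1 and 142 in replicate 2 (log2 ratio -2.50, interval -2.53 to -2.47). Itln1, a lectin gene, had 34.0 and 2.30 TPM (log2 ratio -3.87, interval -4.13 to -3.64), and Lce1m, a cornified envelope gene, had 150 and 15.7. The remaining lowest ratios belonged to Lyg1, Hist1h2an, Rnf227, Ly6k, Retnlg, Gadd45gip1, Xpa, Hcst and Gm21887. Of these, Hist1h2an was left open by reads shared with other genes, with a posterior standard deviation of 14.1% of the count in replicate 1 and 36.6% in replicate 2. Gm21887 (X chromosome, 170009659 to 170019281) had 15832 read pairs in replicate 1 and 2 in replicate 2 (log2 ratio -12.15, interval -16.27 to -11.37).

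In the other direction, Try4, a trypsin gene, had 57.8 TPM in replicate 1 and 185 in replicate 2 (log2 ratio 1.69, interval 1.62 to 1.77), and Tpsab1, a mast cell tryptase gene, had 5.77 and 30.6 (log2 ratio 2.21, interval 2.06 to 2.37). Tm6sf2 had 4.41 and 17.8 TPM, and Tgfbr3l 14.8 and 51.3. Btnl9 had a log2 ratio of 1.61 by scaled counts but 0.70 by TPM with a pseudocount of 1, below the 2-fold limit, at 6.41 and 11.1 TPM. The mitochondrial genes mt-Nd5 and mt-Nd6 had log2 ratios of 1.75 and 1.95. The ribosomal protein genes Rpl30 and Rps27 had log2 ratios of 2.01 and 1.87. Gm20431, Hmga1b and mt-Nd4l were higher too, but reads shared with other genes left their counts open, with a posterior standard deviation in replicate 1 of 110%, 15.8% and 125% of the count.

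Several gene lists differed as groups between the replicates. Of 33 lists with enough members, 8 lay above the middle 95% of expression-matched lists in replicate 2 and 5 below it. All 13 mitochondrial genome mRNAs had a higher scaled count in replicate 2, with a median log2 ratio of 1.33 and, for example, mt-Co1 at 5558 against 3040 TPM and mt-Cytb at 991 against 433. By TPM the direction of mt-Atp8 was the opposite, at 136 against 147. All 5 detected chief cell genes were higher (median 0.55), as were all 7 endothelial genes with a mean TPM of at least 1 (median 0.58, except that Vwf, with a ratio near 0, was lower by TPM at 26.8 against 32.0), 6 of 7 fibroblast genes (median 0.54, Dpt at 30.7 against 18.8 TPM) and 7 of 9 pit cell genes (median 0.29, Muc5ac at 895 against 500). Proliferation genes had a median of 0.58 with 4 of 6 higher, ribosomal protein genes 0.21 with 6 of 10 higher, and pancreas acinar genes 0.27 with 6 of 10 higher. The SD over members was 0.53, 0.56 and 0.78 in these lists. The summed TPM went the other way for ribosomal protein genes, at 4143 in replicate 2 against 5948 in replicate 1, where the most abundant member Rps2 had a log2 ratio of -1.02, and also for proliferation genes (62.7 against 67.2) and pit cell genes (71566 against 73128).

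Red blood cell, mast cell and MHC class II genes were lower in replicate 2. All 4 red blood cell genes were lower, with a median log2 ratio of -1.41 and Hba-a1 at 77.8 against 261 TPM. All 5 mast cell genes were lower (median -0.99, Mcpt1 at 15.1 against 43.4), in contrast to Tpsab1 above. All 6 MHC class II genes were lower (median -0.91, H2-Ab1 at 135 against 346). All 9 immediate early and heat shock genes were lower (median -0.70, Dusp1 at 21.7 against 41.6), as were all 5 acid regulation receptors (median -0.53), although Chrm3 was higher by TPM at 3.97 against 3.57. The proliferation and acid receptor lists lay within the middle 95% when ratios came from TPM (percentiles 92.4 and 10.9). The acid receptor and acinar lists did so at a mean TPM of at least 5 (percentiles 3.17 and 96.9), and the proliferation list with means over members (percentile 97.3). With 1 member left out, the acinar, ribosomal protein and acid receptor lists reached percentiles of 91.1, 96.9 and 4.12. Pit cell genes did so after correction for GC content and length (percentile 97.1) and acinar genes with random lists matched on GC content as well (percentile 97.0), both alternatives added after the data were seen. After that correction striated muscle and interstitial cell of Cajal genes, within the middle 95% as measured (percentiles 94.4 and 96.7), lay above it (both at percentile 99.9).

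**Figure D3:**
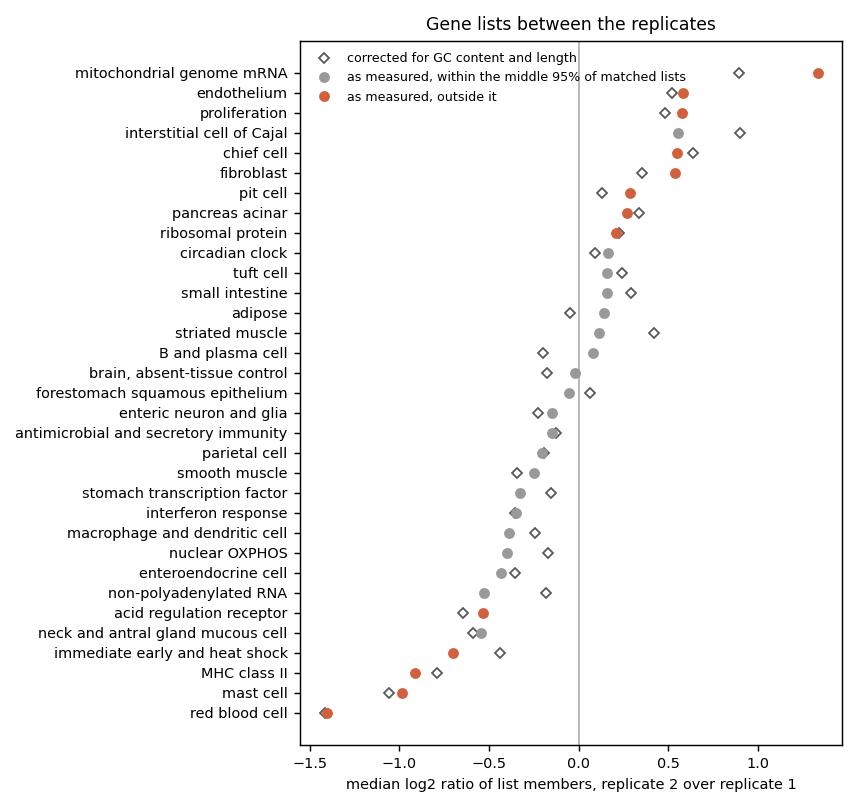
Median log2 ratio of list members, replicate 2 over replicate 1, for the 33 lists with at least 3 members at a mean TPM of at least 1; filled points are as measured and open diamonds are corrected for GC content and length. Mitochondrial genome mRNAs lie at 1.33 and red blood cell genes at -1.41.

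The ratio between the replicates also followed the GC content of transcripts. Over 6769 protein-coding genes with a mean TPM of at least 5, the Spearman correlation with GC content was -0.30 and that with transcript length 0.12, both across genes. The median log2 ratio was 0.07 in the 677 genes with the lowest GC content and -0.48 in the 677 with the highest. The correction for GC content and length, fitted on 10954 protein-coding genes with a mean TPM of at least 1, took the correlation with GC content from -0.36 to 0.04 over those genes. Over the 6769 genes it left a correlation of 0.11, with a median of -0.14 in the group of lowest GC content and -0.01 in that of the highest.

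**Figure D4:**
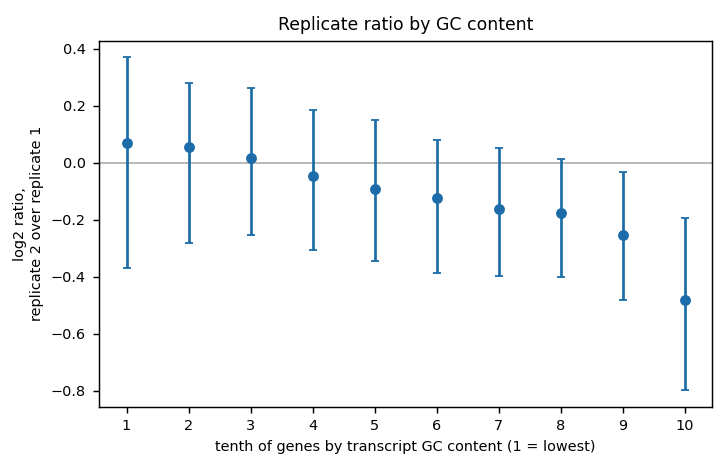
Median log2 ratio, replicate 2 over replicate 1, in 10 equal groups of 6769 protein-coding genes ordered by GC content; bars run from the lower to the upper quartile of genes. The median lies at 0.07 in the group of lowest GC content and at -0.48 in that of the highest.

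For most genes the replicates shared their dominant transcript. Among 5210 genes with a mean TPM of at least 5 and at least 2 transcripts, 4478 (86.0%) had the same dominant transcript in both replicates. Gnas, the stimulatory G protein gene, gave 77.3% ± 5.01 to 1 transcript, Ezr 99.98% ± 0.0316 and Kcnq1, the potassium channel gene, 97.8% ± 2.57. Smtn gave 53.5% ± 2.99, Ctnnd1 51.2% ± 11.5, Synpo2 51.1% ± 4.64, Tpm1 43.1% ± 3.26 and Vegfa 30.2% ± 0.444 to their leading transcript. Actn1 gave 65.3% ± 7.38, Enah 64.3% ± 6.70, Mbnl1 35.4% ± 1.58 and Fgfr2 27.0% ± 3.75. The replicates did not share the leading transcript of Cd44: that of 5045 bases held 32.4% in replicate 1 and 21.6% in replicate 2, and that of 2848 bases held 24.5% and 36.2%. The largest differences in a share were those of Gm21887, whose shares in replicate 2 rested on 2 read pairs, and of Bola3, Fkbp4, Capzb and Ubald2. One Fkbp4 transcript of 2217 bases held 99.9% in replicate 1 and 18.2% in replicate 2, and one Capzb transcript of 1702 bases held 0.913% and 80.6%. That Fkbp4 transcript had 16222 read pairs in replicate 1, but the 10 introns matched for the gene had only 6 to 1072 junction reads over both replicates. The 9 matched introns of Capzb had 1 to 9476. Whether these shares reflect splicing or the model's division of reads was not tested. Bola3 had 436 and 465 read pairs but 5.70 and 73.1 TPM, with 92.5% of replicate 2 assigned to a transcript of 189 bases on 21 read pairs.

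Splicing of the abundant genes was seen directly in the mm9 tables, which the authors made over both replicates. Of 340787 junctions, 82386 passed the limit of 0.1 on the significance field, and these held 98.5% of the 50833838 junction reads. Their median was 65 reads and their median length 1003 bases. The 320-base intron of Clps (chromosome 17, minus strand, 28695386 to 28695705 on mm9) had 1666977 reads and its 1687-base intron (28695829 to 28697515) had 2053959, of which 1766494 were in R2. The 724-base intron of Pgc (chromosome 17, plus strand, 47866319 to 47867042 on mm9) had 4844044 reads. Of 332255 contigs, 150579 passed the limit of 0.1. They covered 62.9 megabases with a median length of 316 bases. The strongest contig (chromosome 17, minus strand, 28695000 to 28696130 on mm9) held the 320-base Clps intron and had a deposited signal of 49300. Its summed coverage stood at the field's highest value.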

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

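The tests on Clps, that on males and that on other genes within the GC range of a list were chosen after their results or the first GC results were seen, while the other tests on GC content and that on loss of long transcripts, apart from its genes of at least 10000 bases, were chosen after the GC trend, the list ratios and the Xist counts had been seen but before their own results. The measure of spread in the GC tests, 2 standard errors (SE) over members, was settled after the values were seen. For mitochondrial mRNAs the choice decides, since the corrected median exceeded 2 SE but not the SD over single members. The SE is the SD over members divided by the square root of their number. It is that of a mean and takes members as independent, so it is only a rough guide to the spread of a median.

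Reads of the phage phiX174, which belong to no mouse gene and enter no comparison, were counted at 131769 read pairs in replicate 1 and 115787 in replicate 2, far above the 3 read pairs that a count of 0 allows.

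Mitochondrial genome mRNAs were higher and red blood cell and MHC class II genes lower in replicate 2, in libraries whose ratios also followed GC content. The GC trend as the whole cause is argued against for red blood cell genes, at percentile 0.030 of random lists matched on expression and GC content and a median of -1.42 (SE 0.08) after correction against -1.41 before, and for MHC class II genes, at percentile 0.070 and -0.79 (SE 0.11) against -0.91. For mitochondrial mRNAs the percentile was 100, although the smallest matched bin held 20 genes, and after correction the median was 0.89 (SE 0.32, SD over members 1.15) against 1.33, with all 13 members above 0. The 195 other genes within their GC range of 31.9% to 41.1% had a median log2 ratio of 0.36, so the trend may give part of the difference but is argued against as all of it; what the correction left, a median of -0.14 in the group of genes of lowest GC content, ran the other way. Reads shared with other genes, which left the counts of mt-Co3 and mt-Nd4l open, were not tested as a cause for the mitochondrial list. The design names no biological difference between the replicates, and no biological explanation was tested.

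Clps was the most abundant transcript although it is known mainly as a pancreatic gene. Pancreatic acinar tissue in the samples is argued against by the other 15 acinar genes of the list, whose median was 2.43 TPM, at most 1.27e-05 of the level of Clps in either replicate. The argument covers the listed genes only. The list does not hold the secreted phospholipase gene Pla2g1b, at 27215 ± 9262 TPM, or the trypsin gene Try4. Reads shared with another gene are argued against by a posterior standard deviation of at most 4.84e-05% of the Clps count. Expression of Clps by cells of the stomach therefore remains as a hypothesis, which may be tested by locating the transcript in tissue.

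Xist had 12 read pairs over both libraries although the labels describe pools of males and females. A complete loss of AT-rich and long transcripts is argued against. At least 100 read pairs fell on 72.2% of 335 genes within 2 points of the GC content of Xist and at least 5000 bases long. At least that many fell on 70.4% of the 27 of at least 10000 bases. Only 2 of these genes, both with that many read pairs, were as long as Xist. Since 100 read pairs show presence alone, a partial loss is not argued against. That the libraries hold RNA of males alone remains a candidate explanation. The 1199 read pairs on 4 Y-linked genes show RNA of males but would also arise from a pool of males and females. The level that Xist would have in a mixed pool was not measured here. The labels name both sexes for each pool, and these data do not resolve the sex of the animals.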

How the results depend on the processing

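Of the alternatives, correction for GC content and length, random lists matched on GC content, and leaving Clps and Pgc out of the total were chosen after seeing the data, those on GC content after the GC trend but before their own results. No median ratio of a list outside the middle 95% changed its sign after the correction for GC content and length. The causes of the changes below were not tested unless given. The Pearson correlation was 0.985 with a pseudocount of 0.1, 0.963 for genes with a mean TPM of at least 1 and 0.982 with posterior means, for which the Spearman correlation was 0.971. A minimum TPM of 5 left 6606 detected genes. The coefficient of variation was 0.361 with no filter except a count above 0, 0.25 at a mean TPM of at least 5 and 0.164 from the DESeq2 median, which also lay below the value put in when tested on simulated data. The 10 most abundant genes held 36.1% of expected counts, or 27.0% of TPM with Clps and Pgc left out, and the 100 most abundant 49.5% and 49.9%. Lists below the middle 95% numbered 0 with all protein-coding genes as the pool, 4 with means over members and 15 with random lists from expressed genes, which hold no silent genes. Without 1 replicate this count was 0 or 1, genes detected ranged from 11358 to 11659, lists above from 16 to 17, and the shares of the 10 and 100 most abundant genes from 47.2% to 58.1% and 65.0% to 71.3%. Genes at least 2-fold higher in replicate 2 numbered 321 at a mean TPM of at least 1 and 29 at 20 or more, and those higher in replicate 1 657 and 281; after correction for GC content and length 68 were higher in replicate 2 and 325 in replicate 1. The share with the same dominant transcript was 83.9% at a gene TPM of at least 1, 87.2% at 20 and 88.6% from expected counts. Without a limit on the significance field there were 340787 junctions and 332255 contigs, and 98806 contigs at 0.01. Spike-ins held 1.13% of expected counts, with a Pearson correlation of 0.991. Values counted as moved were those beyond 1 SD between the replicates for TPM, beyond the SD of the percentiles of the single replicates for level percentiles, beyond the scaled median absolute deviation over members for median ratios of lists, and outside the counting interval for ratios of genes. Of the TPM of single genes 35 values moved and 820 did not, of level percentiles of lists 70 moved and 164 did not, of median log2 ratios of lists 8 moved and 220 did not, and of log2 ratios of single genes 24 moved and 72 did not. Some lists within the middle 95% as reported lay outside it elsewhere. For levels, means over members put enteroendocrine (percentile 97.6) and pancreas acinar genes (98.8) above. For ratios, with means over members, adipose (percentile 99.0), interstitial cell of Cajal (98.7) and striated muscle genes (99.9) lay above and enteroendocrine (1.81) and antimicrobial genes (1.24) below. At a mean TPM of at least 5, B and plasma cell genes lay at percentile 100 and enteric neuron and glia genes at 1.14, and with no minimum B and plasma cell and interferon response genes lay at 0.975 and 1.08. No paired analysis was possible because there is 1 group. Values of genes with few read pairs, such as Xist, are limited in precision.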

Other observations

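Prss2, Amy2a5 and the junctions named here were singled out after their values were seen, and no explanation was tested for them. Several liver genes, low in both libraries, had more read pairs in replicate 2. Alb, the serum albumin gene, had 8 read pairs in replicate 1 and 77 in replicate 2, Cyp2e1 3 and 64, and Serpina3k 0 and 58, all below TPM 1. Among pancreatic genes Prss2 had 15 and 104 read pairs and Amy2a5 2.75 and 27.1. Ahsg, the most abundant liver gene of the list, had 113 and 168.

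The introns of Clps differed between the replicate numbers of the junction table. The 320-base intron had 641432 reads in R1 and 1025545 in R2, while the 1687-base intron had 287465 and 1766494, a ratio of 6.15 against 1.60. In Pla2g1b the 1051-base intron had 176530 and 162010 reads, and the 4461-base intron of that gene had 183532 and 419823. Among 593 junctions with more than 5000 reads the log2 ratio of shares had an SD of 0.77, and 9 lay beyond 2 in either direction. A junction on chromosome 11 (58192601 to 58193146 on mm9), not matched to a gene here, had 6630 reads in R1 and 7 in R2.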
